A study of Homo sapiens with 8 samples.

How the data were processed

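The samples were human memory CD4 T cells sorted into 4 subsets and studied on 8 Affymetrix human gene arrays, 2 per subset. Per the labels, the sorted cells were CD45RO+, CCR7lo and CD25-, and the chemokine receptors CCR6 and CCR4 divided them: Th1 cells were CCR6- and CCR4lo, Th2 cells CCR6- and CCR4hi, Th17 cells CCR6+ and CCR4hi, and Th17.1 cells CCR6+ and CCR4lo. The labels disagree on CXCR3 in Th2 and Th17.1 cells: the characteristics give Th2 as CXCR3+ and Th17.1 as CXCR3-, and the source names give the opposite. The CXCR3 transcript was therefore used as a description, and no group rests on it. All cells were stimulated with beads carrying antibodies to CD3 and CD28 for 36 h at 200000 cells per well. The description gives 2 beads per cell and the growth protocol 1 bead per cell, so the ratio used is open. Each subset holds arrays numbered 2 and 3. No label says whether the numbers stand for donors, sorts or days, so p-values measure only the spread between these arrays, which may be technical.

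The submitters' processing notes name RMA and Affymetrix Power Tools, without a version or a role in the sources used here. RMA is a method that corrects background, normalizes arrays by quantiles and summarises the probes of a gene. The deposited values are intensities on a linear scale, from 0.8589 to 7980.588, with array medians between 76.3 and 80.7 and lower quartiles between 21.4 and 24.0. No background level was used here, so differences against a subset mean near or below these quartiles are given in log2 units without a fold. The design fixed before the data were examined assumed log2 values. Log2 was therefore taken of each intensity, with no pseudocount since all were above 0, and the planned test was kept. Single low values weigh heavily on the log2 scale, and 5 of the values lay under 1. Arrays give no count depth, so their number limits the precision. No 2 arrays were alike enough to be the same hybridisation: the highest correlation between any 2 over all rows was 0.995, and within a subset it was 0.990.

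Gene names came from the platform annotation supplied with the value table, with symbols updated through gene identifiers. Of 22148 rows, 19130 had 1 symbol, 1734 had several and 1284 had none. Rows of X-inactivation and Y-linked genes, 94 in all, were left out because the cells came from people. The remaining 22054 rows were tested, covering 18255 named genes. For the 625 genes with several rows, the row with the highest mean stood for the gene.

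Differential expression was tested with limma 3.58.1 in R 4.3.3. A linear model with 4 subset means was fitted to all 8 arrays, with a variance prior that follows intensity, and left 4 residual degrees of freedom. Contrasts were the 6 pairwise differences, CCR6+ against CCR6- subsets, CCR4lo against CCR4hi subsets, and the interaction of CCR6 with CCR4. A moderated F test asked for any difference among subsets. P-values were adjusted by the Benjamini-Hochberg method over the rows of each contrast, with a threshold of 0.05. Errors of log2 differences are the model's standard errors (SE), and errors of subset means are SDs over 2 arrays. Transcripts of the sorted receptors were also compared, 4 arrays against 4, by two-sided exact permutation tests.

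Gene lists, 23 in all, were fixed before the data were examined. They covered Th1, Th2, Th17, Treg and Tfh genes, cytotoxicity, naive and central memory genes, ABC transporters, glucocorticoid response, T cell activation, secreted cytokines and chemokines, chemokine receptors and integrins, cell cycle, interferon-stimulated genes, cholesterol synthesis, and glycolysis and hypoxia. Further lists held markers of B cells, monocytes and dendritic cells, NK cells, CD8 T cells, MAIT and gamma-delta T cells, and platelets and red cells, the remaining list being the sort markers. Lists overlap. The 21 lists with at least 5 measured genes were tested, apart from the sort markers, with camera, which compares a list's members with all other genes at a preset inter-gene correlation of 0.01. For each list the members past the threshold were also counted, adjusted over the list alone. Camera calls were repeated with the correlation estimated from the residuals. None of the 69 calls over 9 contrasts held then, nor with limma's fry, which asks whether a list moves one way on balance. In none of these calls did the median, the mean and the direction of the test differ in sign, against 36 of the 120 tests without a call.

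Genes were named by a rule set beforehand: the 10 largest differences each way among rows past the threshold with non-overlapping groups, or the 5 largest non-overlapping differences each way as values where fewer than 5 rows passed, plus sort markers, ABCB1, lineage cytokines and regulators, and up to 4 members per list with the smallest p. HLA genes, receptor and immunoglobulin segments and common deletion loci were left unnamed.

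Whether the replicate numbers pair the arrays was checked by a rule set beforehand. Deviations of same-numbered arrays from their subset means correlated over all rows at 0.141 to 0.551 in the 6 pairs of subsets, each above the minimum of 0.1, and the first principal component, with 35.9% of the variance, separated the numbers. The numbers were therefore taken to pair the arrays, on the data alone. The main fit was planned without a block and kept, so SEs, counts and camera p-values ignore this pairing unless the blocked fit is named. The fit with the number as a block left 3 residual degrees of freedom and lowered the median residual SD from 0.189 to 0.145. Other alternatives were centring each array on its median, cyclic loess, leaving out the dimmest 40% of rows, other variance priors, fits of the compared arrays alone, the mean of a gene's rows, and leaving out each array in turn. A subset left with 1 array was then assumed to vary like the others. These leave-one-out fits held no block, so a lone array's replicate number is mixed with its subset.

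The fit was tested on simulated data made from the real means and residual spreads, over 22054 rows with 200 genes changed in the Th17.1 arrays. In the Th17.1 against Th2 contrast it recovered 56% of changes of 1 log2 unit and 96% of changes of 2, with 9 false calls. In the CCR6 contrast, where a change in Th17.1 is diluted, it recovered 10% and 84%, with 4 false calls. The simulation held no difference between replicate numbers. Its changed genes were drawn at random from all rows, and many genes named below had larger errors than a typical row. In the real Th17.1 against Th2 contrast IL5, IL17RB, IL31 and IL13 differed by more than 2 log2 units without a call. The simulated recovery therefore does not hold for such genes, and an absent call does not speak against a large change. Of 20 simulated lists over 18255 genes in the Th17.1 against Th2 contrast, 5 were shifted and all 5 were recovered by camera with the preset and with the estimated correlation, without a false call. The simulated genes varied independently of each other, so this tests no list whose members are correlated. Figures were drawn with matplotlib 3.10.9.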

Results

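Transcript levels were measured in 4 subsets of human effector memory CD4 T cells after 36 h of stimulation through CD3 and CD28: Th1, Th2, Th17 and Th17.1 cells. The sort crossed CCR6, a receptor carried by cells of the Th17 lineage, with CCR4, a receptor found on Th2 and Th17 cells. Each subset had 2 arrays, numbered 2 and 3, and values are log2 intensities with array medians from 6.25 to 6.33. The comparisons ask how the subsets differ from each other, what goes with CCR6 and what goes with CCR4.

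Transcripts of the sorted receptors followed the sort. CCR6 measured 7.49 ± 0.20 (SD, n = 4) in CCR6+ arrays and 5.76 ± 0.77 (SD, n = 4) in CCR6- arrays. CCR4 measured 10.17 ± 0.14 in CCR4lo arrays and 11.06 ± 0.21 in CCR4hi arrays, over 4 arrays each. CXCR3, the receptor on which the labels disagree, measured 8.59 ± 0.47 in the CCR4lo subsets and 7.18 ± 0.44 in the CCR4hi subsets, again over 4 arrays each. By subset it was 8.80 ± 0.63 in Th1, 7.35 ± 0.11 in Th2, 7.02 ± 0.67 in Th17 and 8.37 ± 0.30 in Th17.1 cells. For these 3 receptors every array of one arm lay above every array of the other, which gave the smallest two-sided exact permutation p that 70 splits allow, 0.0286, or 0.0571 after adjustment over 6 tests. CCR7, IL2RA and CD4 did not separate the CCR6 arms, with exact permutation p of 0.171, 0.0857 and 0.8. These splits took no account of the pairing by number.

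**Figure D1:**
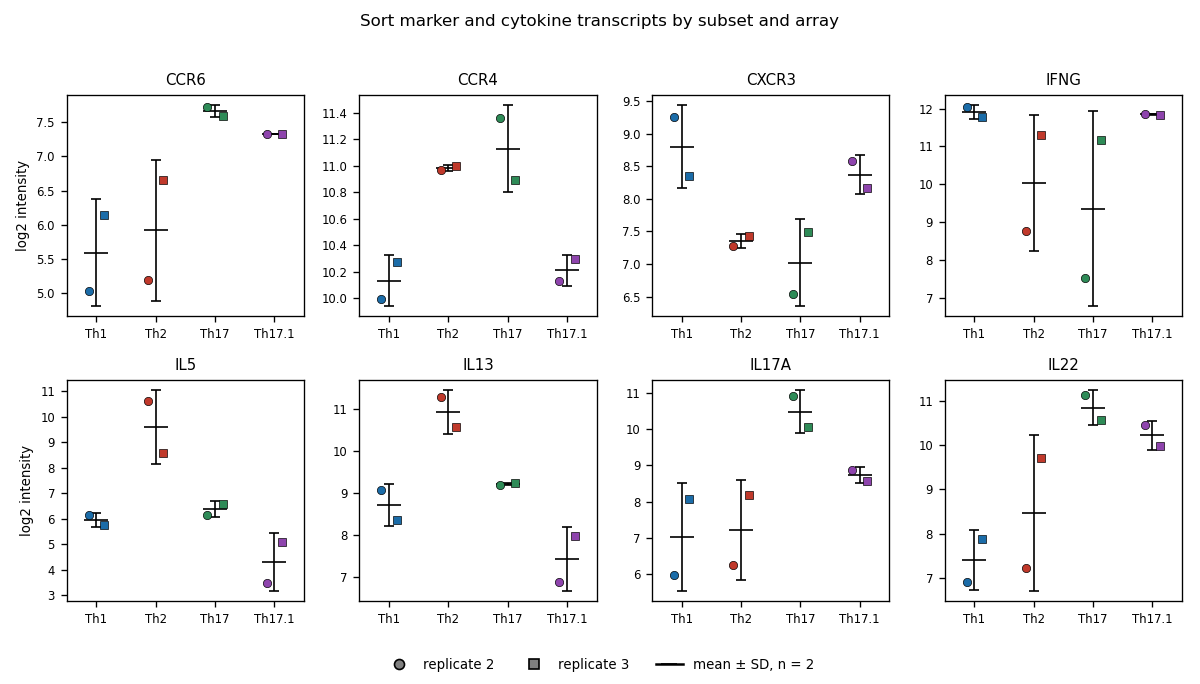
Log2 intensity (y axis) of 3 receptors named in the labels and 5 cytokines in the 4 subsets (x axis), with circles for arrays numbered 2, squares for arrays numbered 3, and bars for the mean ± SD of 2 arrays. IL5 and IL13 are highest in Th2 cells, IL17A is highest in Th17 cells, and IFNG ranges from 7.52 to 12.04 in the arrays numbered 2 but from 11.17 to 11.85 in those numbered 3.

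The CCR6 comparison parted cytokines of the Th17 program from type 2 cytokines. IL22, a cytokine acting on epithelium, was 6.08-fold higher (log2 difference 2.60 ± 0.51 SE), and CCL20, the ligand of CCR6, was 4.68-fold higher (2.23 ± 0.40). IL23R, the receptor that sustains Th17 cells, had a log2 difference of 1.38 ± 0.16, and the protease gene CTSH one of 2.03 ± 0.31. In the other direction stood the type 2 cytokine genes IL4 (-2.02 ± 0.37) and IL5 (-2.43 ± 0.49). Between CCR6+ Th17 and CCR6- Th1 cells, which also differ in CCR4, the Th2 list had a median of 0.033 (camera adjusted p = 0.381). Of the 26 measured Th17 genes, 19 had a higher mean in CCR6+ cells and 9 passed the threshold adjusted over the list alone, all higher, although none passed over all rows. Camera placed the list above other genes (median 0.39, adjusted p = 5.71e-09, and adjusted p = 0.131 with an estimated correlation).

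Across all 22054 rows, limma called none between CCR6+ and CCR6- cells, the smallest adjusted p being 0.335, and 704 rows had an unadjusted p under 0.05 where 1103 are expected by chance. The fit behind these 704 rows leaves the difference between replicate numbers in its error, so its count does not show fewer differences than chance. The blocked fit also called none, with 1353 rows at an unadjusted p under 0.05, above those 1103. Rows are correlated with each other, so neither count is a test. Rows whose 4 arrays lay wholly above or below the other 4 made up 2.73%, against 2.86% by chance. The remaining leading differences by size were IL17A (2.49 ± 0.55), whose product defines Th17 cells, and ADAM12 (2.21 ± 0.50), and on the lower side IL24 (-1.80 ± 0.54), XCL1 (-1.38 ± 0.33), TIGIT (-1.05 ± 0.22) and PHEX (-0.99 ± 0.25).

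Other lists also moved with CCR6. Of 22 Th2 genes, 16 were lower in CCR6+ cells and 4 passed adjusted over the list alone, namely IL4, IL5, IL13 and IL31 (camera adjusted p = 1.71e-06, and adjusted p = 0.131 with an estimated correlation). That count was 7 without Th2 replicate 3 or without Th17 replicate 3, and 1 in a fit of 4 arrays against 4. Secreted cytokines and chemokines changed in both directions, with 13 of 34 past the threshold adjusted over the list alone (8 in a fit of 4 arrays against 4) and a median of -0.34 (camera adjusted p = 0.00362, and adjusted p = 0.301 with an estimated correlation). Their call was lost without Th17 replicate 2, at an adjusted p of 0.0546. All 22 glycolysis and hypoxia genes had a higher mean in CCR6+ cells, by a median of 0.11, and 31 of 32 cell cycle genes a lower mean, by a median of -0.14, and no member of either list passed adjusted over the list alone. Camera gave adjusted p of 0.000493 and 2.56e-05 for these lists, and both had an adjusted p = 0.666 with an estimated correlation. Without Th2 replicate 2 the adjusted p became 0.836 and 0.424, and without Th17 replicate 3 that of the cell cycle genes became 0.157. Tfh genes were lower by a median of -0.07 (adjusted p = 0.0221, and adjusted p = 0.380 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. The Tfh call was lost, with adjusted p of 0.170, 0.0537, 0.0966, 0.115 and 0.0800, without Th1 replicate 3, Th2 replicate 2, Th2 replicate 3, Th17 replicate 2 and Th17.1 replicate 2.

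CCR4lo cells, the Th1 and Th17.1 subsets, carried more transcript of cytotoxic effector genes than CCR4hi cells. Of 18 measured cytotoxicity genes, 17 had a higher mean and 13 passed the threshold adjusted over the list alone, with a median difference of 1.14. SLAMF7, an activating receptor of killer lymphocytes, was 3.83-fold higher (1.94 ± 0.37), and the granule gene NKG7 (1.12 ± 0.23), the transcription factor gene EOMES (1.35 ± 0.31) and the inhibitory receptor gene KLRG1 (1.25 ± 0.29) stood on the same side. Camera gave an adjusted p of 7.05e-22 for the list (adjusted p = 0.102 with an estimated correlation). Leaving out Th17.1 replicate 2 lowered the count from 13 to 4. Markers of other cytotoxic cells lay on the same side: 8 of 9 MAIT and gamma-delta T cell markers had a higher mean in CCR4lo cells, by a median of 0.64 (camera adjusted p = 2.50e-05, and adjusted p = 0.199 with an estimated correlation), and 8 of 12 NK cell markers, by a median of 0.14 (camera adjusted p = 0.0341, and adjusted p = 0.169 with an estimated correlation). The NK median was -0.29 for Th2 minus Th1 but -0.007 for Th17.1 minus Th17, so the CCR6+ subsets hardly differed in it. Adjusted over the list alone, 1 MAIT marker, IL18RAP, which is also in the Th1 list, and 0 NK markers passed. The MAIT count was 3 in the blocked fit, 0 without Th1 replicate 2, Th2 replicate 2 or Th17.1 replicate 2, 3 without Th2 replicate 3 or Th17 replicate 3, and 4 without Th17.1 replicate 3. The NK call was lost without Th2 replicate 3, Th17 replicate 3, Th17.1 replicate 2 and Th17.1 replicate 3, at adjusted p of 0.103, 0.154, 0.101 and 0.0670.

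Type 2 genes lay on the CCR4hi side. IL17RB, the receptor for interleukin-25, had a log2 difference of -3.63 ± 0.34 between CCR4lo and CCR4hi cells, with subset means of 8.59 ± 0.61 in Th2 and 8.29 ± 0.53 in Th17 cells against 5.14 ± 0.45 in Th1 and 4.48 ± 0.86 in Th17.1 cells. IL5 (-2.86 ± 0.49), IL13 (-2.00 ± 0.29), the chemokine receptor gene CCR8 (-2.15 ± 0.31) and the choline dehydrogenase gene CHDH (-1.84 ± 0.27) followed. Of 22 Th2 genes, 8 passed adjusted over the list alone, all lower in CCR4lo cells (camera adjusted p = 5.12e-10, and adjusted p = 0.0663 with an estimated correlation). Of 23 Th1 genes, 7 passed adjusted over the list alone, all higher, among them IL12RB2 (0.62 ± 0.10), a chain of the interleukin-12 receptor, CCL5 (1.63 ± 0.32), HAVCR2 (1.26 ± 0.27) and IL18RAP (2.30 ± 0.52). Camera gave this list an adjusted p of 3.55e-13 (adjusted p = 0.0872 with an estimated correlation). IFNG, the Th1 cytokine, had a log2 difference of 2.19 ± 0.80 and did not pass adjusted over the list alone.

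No row passed in limma over all rows for CCR4lo against CCR4hi cells, with 823 rows at an unadjusted p under 0.05 (1362 in the blocked fit, which also called none). Non-overlapping rows made up 2.63%, against 2.86% by chance. IL17RB came nearest, with an adjusted p of 0.0686, and was the only call in a fit of 4 arrays against 4, at an adjusted p of 0.0173, while over all 15 alternatives its adjusted p lay between 0.0173 and 0.495. Calls appeared when either Th17 array was left out. Those fits set a lone array against subsets holding both numbers, so they mix subset with replicate number. Further leading differences were DTHD1 (2.40 ± 0.69) and PLEK (1.90 ± 0.40) on the CCR4lo side and SEPTIN10 (-2.30 ± 0.55) on the CCR4hi side.

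Treg and Tfh genes were lower in CCR4lo cells as lists. In the Treg list 3 of 17 members passed adjusted over the list alone, RTKN2 (-1.72 ± 0.29), CCR10 (-1.16 ± 0.30) and IKZF2 (-1.24 ± 0.35), and none of these is specific to Treg cells, CCR10 being a skin-homing receptor. FOXP3, the regulator of Treg cells, measured 9.36 ± 0.46 in Th1, 9.09 ± 0.33 in Th2, 9.85 ± 0.50 in Th17 and 9.81 ± 1.21 in Th17.1 cells. Camera gave the Treg list an adjusted p of 4.69e-06 and the Tfh list one of 0.000176 (adjusted p = 0.0663 and adjusted p = 0.102 with an estimated correlation). The Treg count was 5 in the blocked fit and 1 with the dimmest rows left out, and 1 without Th1 replicate 2, either Th2 array or either Th17.1 array. In the Tfh list 0 of 13 members passed. Secreted cytokines were lower by a median of -0.25 (camera adjusted p = 2.50e-05, and adjusted p = 0.0872 with an estimated correlation). Past the threshold adjusted over the list alone were 6 of 34, IL5, IL13, IL31 and TNFSF11 lower and CCL3 and CCL5 higher. Their count was 12 without Th2 replicate 3, 10 without Th17 replicate 3, 2 without Th17.1 replicate 2 and 1 in a fit of 4 arrays against 4. Th17 genes were lower by a median of -0.31 with 0 of 26 past the threshold adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.126 with an estimated correlation), and without Th17.1 replicate 3 the adjusted p was 0.0546. Chemokine receptors and integrins had no camera call (adjusted p = 0.549). The 5 of 25 members past the threshold adjusted over the list alone include CCR4, used for the sort, and CXCR3, named in the labels. That count was 8 in the blocked fit and in a fit of 4 arrays against 4, 9 without Th17 replicate 3, and 3 without either Th1 array, either Th2 array or Th17.1 replicate 2.

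**Figure D2:**
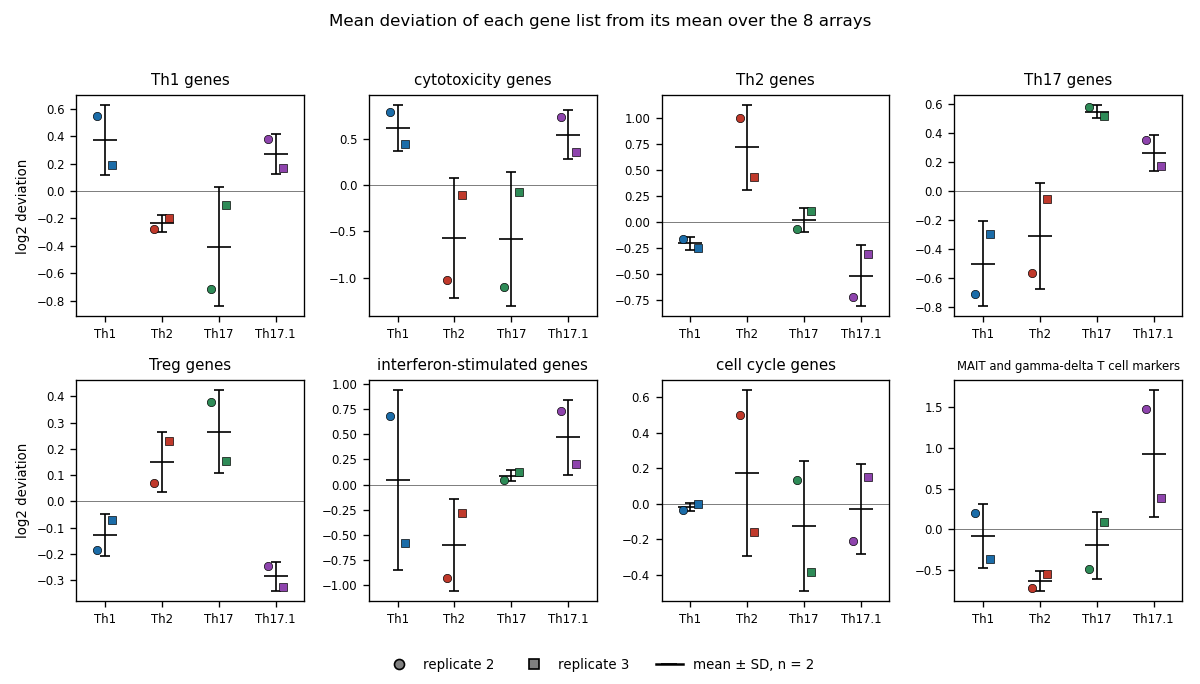
Mean log2 deviation (y axis) of the members of 8 gene lists from each member's mean over all arrays, by subset (x axis), with circles for arrays numbered 2, squares for arrays numbered 3 and bars for the mean ± SD of 2 arrays. Cytotoxicity genes deviate by 0.79 and 0.44 in the Th1 arrays and by -1.03 and -0.11 in the Th2 arrays, so that the subsets lie further apart in the arrays numbered 2.

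The CCR6 and CCR4 differences were also measured in separate cells. Across rows, Th17 minus Th2 correlated with Th17.1 minus Th1 at Pearson r = 0.307 and Spearman rho = 0.187, and Th1 minus Th2 with Th17.1 minus Th17 at r = 0.397 and rho = 0.0567. The members of each pair share no array, and genes are not independent replicates. Within the arrays numbered 2 the Pearson values were 0.345 and 0.467, and within those numbered 3 they were 0.145 and 0.261. The test of the interaction called no row in limma, with 237 rows at an unadjusted p under 0.05 and 537 in the blocked fit. The moderated F test for any difference among the 4 subsets also called none, with 578 rows at an unadjusted p under 0.05 and 1154 in the blocked fit. Without Th17 replicate 3 the F test called 6 rows.

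Th2 cells differed from Th1 cells in type 2 cytokines on one side and cytotoxic genes on the other. IL5 measured 9.58 ± 1.45 (SD, n = 2) in Th2 and 5.94 ± 0.27 in Th1 cells, and IL13 measured 10.92 ± 0.52 against 8.70 ± 0.50. IL17RB (3.45 ± 0.48 SE), IL31 (2.72 ± 0.61), a cytokine linked to itch, and PTGS2 (2.68 ± 0.72), an enzyme of prostaglandin synthesis, completed the largest differences upward. GATA3, the Th2 regulator, measured 9.97 ± 0.54 in Th2 and 9.14 ± 0.11 in Th1 cells. Downward stood GZMK (-2.63 ± 1.16), DTHD1 (-2.41 ± 0.97), PLCB1 (-2.17 ± 0.87), GNLY (-2.13 ± 0.62) and GZMA (-2.07 ± 0.77), of which GZMK, GNLY and GZMA encode proteins of cytotoxic granules.

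Adjusted over the list alone, 8 of 22 Th2 genes were higher in Th2 than in Th1 cells and 7 of 18 cytotoxicity genes and 4 of 23 Th1 genes were lower. Camera gave adjusted p of 2.03e-09, 7.22e-15 and 1.84e-07 (adjusted p = 0.125, 0.211 and 0.211 with an estimated correlation). All 18 cytotoxicity genes had a lower mean. The Th2 count was 4 without Th1 replicate 2, 5 without Th1 replicate 3 and 3 without Th2 replicate 2. The cytotoxicity count was 11 in the blocked fit and without Th2 replicate 3, and 0 without Th1 replicate 2, without Th2 replicate 2 or with the dimmest rows, CRTAM among them, left out. The Th1 count was 0 without Th1 replicate 2, Th2 replicate 2 or either Th17.1 array, and 2 in a fit of these 4 arrays. Over all rows limma called none, with 547 at an unadjusted p under 0.05 and 1027 in the blocked fit, and without Th2 replicate 3 it called 1, HPGDS, a member of the Th2 list named here after its value was seen.

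Th17 and Th1 cells parted in single effector cytokines, in both directions. Of 34 cytokines and chemokines, 8 passed adjusted over the list alone, and camera did not call the list (adjusted p = 0.568). IL17A was 11.0-fold higher in Th17 than in Th1 cells (3.47 ± 0.78 SE). IL22 measured 10.84 ± 0.39 (SD, n = 2) in Th17 and 7.39 ± 0.68 in Th1 cells, and IL26 7.18 ± 0.99 against 3.67 ± 0.77. HRH4, a histamine receptor (3.17 ± 0.89 SE), and IL17RB (3.15 ± 0.48) were next by size. IFNG measured 9.35 ± 2.58 in Th17 and 11.90 ± 0.18 in Th1 cells, and did not pass adjusted over the Th1 or the cytokine list alone. The other large differences downward were DTHD1 (-2.92 ± 0.97), CRTAM (-2.26 ± 0.42), SLAMF7 (-2.06 ± 0.53) and STAP1 (-2.02 ± 0.80).

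Of 26 Th17 genes, 8 were higher in Th17 than in Th1 cells adjusted over the list alone (camera adjusted p = 1.88e-15, and adjusted p = 0.0859 with an estimated correlation), a count of 2 without Th1 replicate 2 and 4 without Th17 replicate 2. Of 23 Th1 genes, 6 were lower (camera adjusted p = 1.32e-10, and adjusted p = 0.168 with an estimated correlation). The Th1 count was 0 without Th1 replicate 2 or Th17 replicate 2, 3 without Th1 replicate 3 or either Th17.1 array, and 10 without Th17 replicate 3. In the cytotoxicity list 17 of 18 members had a lower mean in Th17 cells and 2 passed adjusted over the list alone, SLAMF7 and CRTAM (camera adjusted p = 2.08e-17, and adjusted p = 0.175 with an estimated correlation). The cytotoxicity count was 4 in the blocked fit, 9 in a fit of these 4 arrays and 0 with the dimmest rows left out, which dropped CRTAM itself. It was 0 without Th1 replicate 2, 1 without Th17 replicate 2, 4 without Th1 replicate 3, 6 without either Th2 array and 7 without Th17 replicate 3. Over all rows limma called none, with 578 at an unadjusted p under 0.05 and 1001 in the blocked fit, and without Th17 replicate 3 it called 28.

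Between Th17.1 and Th1 cells no difference in cytotoxicity or Th1 genes was detectable with these arrays. IFNG measured 11.86 ± 0.01 (SD, n = 2) in Th17.1 and 11.90 ± 0.18 in Th1 cells, a log2 difference of -0.05 ± 1.14 SE. Cytotoxicity genes had a median difference of -0.09 and Th1 genes one of 0.02, without a camera call (adjusted p = 0.267 and 0.852) and with 0 members of either past the threshold adjusted over the list alone. ME1, malic enzyme, measured 6.65 ± 1.04 against 3.17 ± 0.48, and SLC4A10, a bicarbonate transporter, 8.19 ± 0.81 against 5.33 ± 0.16. IL22 (2.82 ± 0.72 SE), ADAM12 (2.54 ± 0.71) and PTPN13 (2.36 ± 0.56) were the other leading differences upward. Those downward were XCL2 (-2.21 ± 1.02), FCER1G (-1.75 ± 0.34), IL5 (-1.65 ± 0.69), IL4 (-1.65 ± 0.53) and CRTAM (-1.49 ± 0.42).

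Adjusted over the list alone, 7 of 26 Th17 genes were higher in Th17.1 than in Th1 cells (camera adjusted p = 1.05e-07, and adjusted p = 0.144 with an estimated correlation), a count of 1 without Th1 replicate 2 or either Th17.1 array. Th2 genes were lower by a median of -0.14 with 0 of 22 past the threshold adjusted over the list alone (camera adjusted p = 0.000660, and adjusted p = 0.189 with an estimated correlation), and without Th17.1 replicate 2 the adjusted p was 0.121. In limma no row passed over all rows, 329 had an unadjusted p under 0.05 and 662 did in the blocked fit.

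Th17 and Th2 cells, both CCR4hi, parted by their cytokines. IL17A measured 10.49 ± 0.59 (SD, n = 2) in Th17 and 7.21 ± 1.38 in Th2 cells, and CCL20 11.06 ± 0.40 against 8.47 ± 1.10. IL17F (2.63 ± 1.00 SE), HRH4 (2.49 ± 0.89) and IL22 (2.39 ± 0.72) stood on the same side. IL5 (-3.21 ± 0.69), IL24 (-2.90 ± 0.77), IL31 (-2.82 ± 0.61), IL4 (-2.40 ± 0.53) and PTGS2 (-2.30 ± 0.72) were the largest differences downward. All 32 cell cycle genes had a lower mean in Th17 cells, by a median of -0.28, with 0 past the threshold adjusted over the list alone (camera adjusted p = 3.10e-07, and adjusted p = 0.818 with an estimated correlation). That call was lost without Th2 replicate 2, at an adjusted p of 0.435, and without Th17 replicate 3, at 0.156.

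Of 34 cytokines and chemokines, 13 passed between Th17 and Th2 cells adjusted over the list alone, in both directions. Camera gave the list an adjusted p of 0.00789 with a median of -0.37 (adjusted p = 0.356 with an estimated correlation), but 0.0818 in the blocked fit, 0.126 without Th2 replicate 2 and 0.154 without Th17 replicate 2. The count was 0 without either of those arrays and 20 without Th2 replicate 3. Th17 genes were higher, with 6 of 26 past the threshold adjusted over the list alone and 11 in the blocked fit (camera adjusted p = 2.05e-06, and adjusted p = 0.222 with an estimated correlation). Without Th2 replicate 2 that count was 0, without Th17 replicate 2 it was 2, and without Th2 replicate 3 it was 13. Th2 genes were lower, with 4 of 22 past the threshold adjusted over the list alone (camera adjusted p = 2.58e-05, and adjusted p = 0.222 with an estimated correlation), a count of 0 without Th2 replicate 2 or Th17 replicate 2, 9 without Th2 replicate 3 and 8 without Th17 replicate 3. Over all rows limma called none, with 648 at an unadjusted p under 0.05 and 1330 in the blocked fit.

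Th17.1 and Th2 cells, which differ in both receptors, parted in type 2 genes. IL5 measured 4.30 ± 1.14 (SD, n = 2) in Th17.1 and 9.58 ± 1.45 in Th2 cells, and IL17RB 4.48 ± 0.86 against 8.59 ± 0.61. IL31 (-3.62 ± 0.61 SE), IL13 (-3.50 ± 0.40) and PTGS2 (-3.44 ± 0.72) followed. Upward stood GZMK (3.84 ± 1.16), a granzyme, SLC4A10 (3.62 ± 0.76), ME1 (3.19 ± 0.46), the drug efflux pump gene ABCB1 (2.85 ± 0.52) and IL18RAP (2.77 ± 0.73), a chain of the interleukin-18 receptor. Of 22 Th2 genes, 8 were lower adjusted over the list alone, and the count stayed between 8 and 11 with any array left out (camera adjusted p = 4.80e-12, and adjusted p = 0.0786 with an estimated correlation).

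Interferon-stimulated genes formed the most uniform list between Th17.1 and Th2 cells. All 23 had a higher mean in Th17.1 cells, 22 without overlap, by a median of 0.99, and 0 passed adjusted over the list alone (camera adjusted p = 2.28e-14, and adjusted p = 0.282 with an estimated correlation). IFI44L (2.51 ± 0.81) and IFIT3 (1.70 ± 0.55) are examples. The list's mean deviation differed between arrays of the same subset, at 0.68 and -0.58 in the Th1 arrays numbered 2 and 3, -0.93 and -0.28 in Th2, 0.05 and 0.13 in Th17, and 0.74 and 0.21 in Th17.1. The list was also higher in CCR6+ than in CCR6- cells, by a median of 0.47 (camera adjusted p = 5.71e-09, and adjusted p = 0.565 with an estimated correlation), and in CCR4lo than in CCR4hi cells, by a median of 0.45 (camera adjusted p = 3.71e-10, and adjusted p = 0.355 with an estimated correlation). Against Th1 cells it was higher in Th17.1 cells by a median of 0.36 (camera adjusted p = 8.23e-05, and adjusted p = 0.571 with an estimated correlation). That direction turned without Th1 replicate 3, at an adjusted p of 0.000917, and the call was lost without Th17.1 replicate 2, at 0.596. All 23 had a lower mean in Th2 than in Th1 cells, by a median of -0.52 (camera adjusted p = 8.39e-09, and adjusted p = 0.411 with an estimated correlation). Without Th1 replicate 2 that direction turned, at an adjusted p of 0.607, and without Th2 replicate 2 the call was lost, at 0.0751. Between Th17 and Th2 cells the median was 0.59 (camera adjusted p = 7.52e-07, and adjusted p = 0.818 with an estimated correlation), a call lost without Th2 replicate 2, at 0.112. Between Th17.1 and Th17 cells it was 0.37 (camera adjusted p = 0.000375, and adjusted p = 0.723 with an estimated correlation), a call lost without Th17.1 replicate 2, at 0.557.

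Cytotoxicity genes had a higher mean in Th17.1 than in Th2 cells in 16 of 18 cases, and 8 passed adjusted over the list alone (camera adjusted p = 2.12e-09, and adjusted p = 0.282 with an estimated correlation). This count fell to 0 with cyclic loess, with a variance prior that ignores intensity, and without either Th1 array, Th2 replicate 2 or Th17.1 replicate 2. Of 23 Th1 genes, 20 had a higher mean and 1, IL12RB2, passed adjusted over the list alone, or 8 in the blocked fit and 4 in a fit of these 4 arrays (camera adjusted p = 1.20e-05, and adjusted p = 0.248 with an estimated correlation). The Th1 count was 0 without Th2 replicate 2 or Th17.1 replicate 2, 2 without either Th1 array, 3 without Th17 replicate 3 or Th17.1 replicate 3, 4 without Th17 replicate 2 and 9 without Th2 replicate 3. Over all rows limma called none between Th17.1 and Th2 cells, with a smallest adjusted p of 0.176, 969 rows at an unadjusted p under 0.05, and 1718 in the blocked fit. Leaving out either Th17 array gave 2 calls.

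Th17.1 and Th17 cells share CCR6 and differ in CCR4. GZMK measured 7.75 ± 1.60 (SD, n = 2) in Th17.1 and 4.44 ± 1.70 in Th17 cells, and IL18RAP 8.72 ± 0.95 against 5.76 ± 1.37. SLC4A10 (2.72 ± 0.76 SE), ME1 (2.64 ± 0.46) and IFNG (2.51 ± 1.14) were next. IL17RB (-3.81 ± 0.48), TSHZ2 (-3.10 ± 1.29), SEPTIN10 (-2.91 ± 0.78), ZC3H12C (-2.71 ± 0.56) and CCR8 (-2.42 ± 0.44) were the largest differences downward. IL17A had a log2 difference of -1.76 ± 0.78. The Th17 list was lower in Th17.1 cells, with a median of -0.20, and had 0 of 26 members past the threshold adjusted over the list alone (camera adjusted p = 0.00110, and adjusted p = 0.195 with an estimated correlation), and without Th17.1 replicate 3 the adjusted p was 0.372.

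In the cytotoxicity list 17 of 18 members had a higher mean in Th17.1 than in Th17 cells and 2 passed adjusted over the list alone (camera adjusted p = 1.07e-13, and adjusted p = 0.195 with an estimated correlation), a count of 0 without Th17 replicate 2 or Th17.1 replicate 2 and 7 without Th17 replicate 3. Th2 genes were lower, with 4 of 22 past the threshold adjusted over the list alone (camera adjusted p = 2.19e-05, and adjusted p = 0.171 with an estimated correlation). The Th2 count was 7 without either Th2 array and in a fit of these 4 arrays, 8 without Th17 replicate 3 and 1 without Th17.1 replicate 2. Over all rows limma called none, with 542 at an unadjusted p under 0.05 and 997 in the blocked fit, and without Th17 replicate 3 it called 23.

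Among the markers of other cells that a CD4 gate could hold, those shared with MAIT and gamma-delta T cells stood out in Th17.1 cells. The gamma-delta receptor genes of this list were not measured, so the list does not assess gamma-delta identity. Of its measured markers, KLRB1 is also in the Th17 list and IL18RAP in the Th1 list. SLC4A10, a gene of MAIT cells, measured 8.19 ± 0.81 (SD, n = 2) in Th17.1 and 4.57 ± 0.78 in Th2 cells. Of the 9 measured markers, 6 were higher in Th17.1 than in Th2 cells adjusted over the list alone, and the list had a median difference of 1.33 (camera adjusted p = 2.63e-07, and adjusted p = 0.210 with an estimated correlation). The count was 0 without Th2 replicate 2 or Th17.1 replicate 2. Against Th1 cells all 9 had a higher mean, by a median of 0.98, and 0 passed adjusted over the list alone (camera adjusted p = 1.14e-07, and adjusted p = 0.189 with an estimated correlation), with a camera adjusted p of 0.0895 without Th17.1 replicate 2. Against Th17 cells 2 passed, SLC4A10 and IL18RAP (camera adjusted p = 3.69e-06, and adjusted p = 0.195 with an estimated correlation). That count was 0 without Th17 replicate 2 or Th17.1 replicate 2, 4 without Th17 replicate 3 or Th17.1 replicate 3, and 1 without either Th1 array or in a fit of these 4 arrays. Without Th17.1 replicate 2 the camera adjusted p was 0.308. Between CCR6+ and CCR6- cells 3 of the 9 passed adjusted over the list alone, all higher (camera adjusted p = 5.34e-05, and adjusted p = 0.380 with an estimated correlation), a count of 0 without either Th1 array, Th2 replicate 2 or Th17.1 replicate 2 and of 5 without Th17.1 replicate 3. CD8A measured 6.92 in Th17.1 replicate 2 and 5.78 in Th17.1 replicate 3, and between 5.73 and 6.05 in the other arrays. CD4 measured 10.55 ± 0.02 in Th17.1 cells. Its value of 10.57 in Th17.1 replicate 3 lay below the other subsets of that number, at 10.87 to 11.06. In Th17.1 replicate 2 it was 10.54, against 10.09 to 10.55.

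NK cell markers were lower in Th2, Th17 and Th17.1 cells than in Th1 cells as a list, with medians of -0.29, -0.19 and -0.13. FCER1G, a signalling chain of Fc receptors, was the single member of 12 past the threshold adjusted over the list alone in each of these contrasts, measuring 6.40 ± 0.74 (SD, n = 2) in Th1, 4.95 ± 0.29 in Th2, 4.55 ± 0.01 in Th17 and 4.64 ± 0.39 in Th17.1 cells. Camera gave adjusted p of 0.000412, 0.00908 and 0.000333 (adjusted p = 0.147, 0.168 and 0.144 with an estimated correlation). Leaving out the dimmest rows kept 3 of the 12 markers and dropped FCER1G itself, so that setting does not test it. The Th2 call was lost without Th2 replicate 3 (adjusted p of 0.0537) and the Th17 call without Th17 replicate 3 (adjusted p of 0.198). FCER1G no longer passed in Th2 cells without Th1 replicate 2 or any Th2 or Th17 array, nor under cyclic loess or in a fit of the Th1 and Th2 arrays alone. In Th17 cells it did not pass without either Th17 array, and in Th17.1 cells it did not pass without Th17.1 replicate 2. In the blocked fit 2 members passed in Th2 cells.

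**Figure D3:**
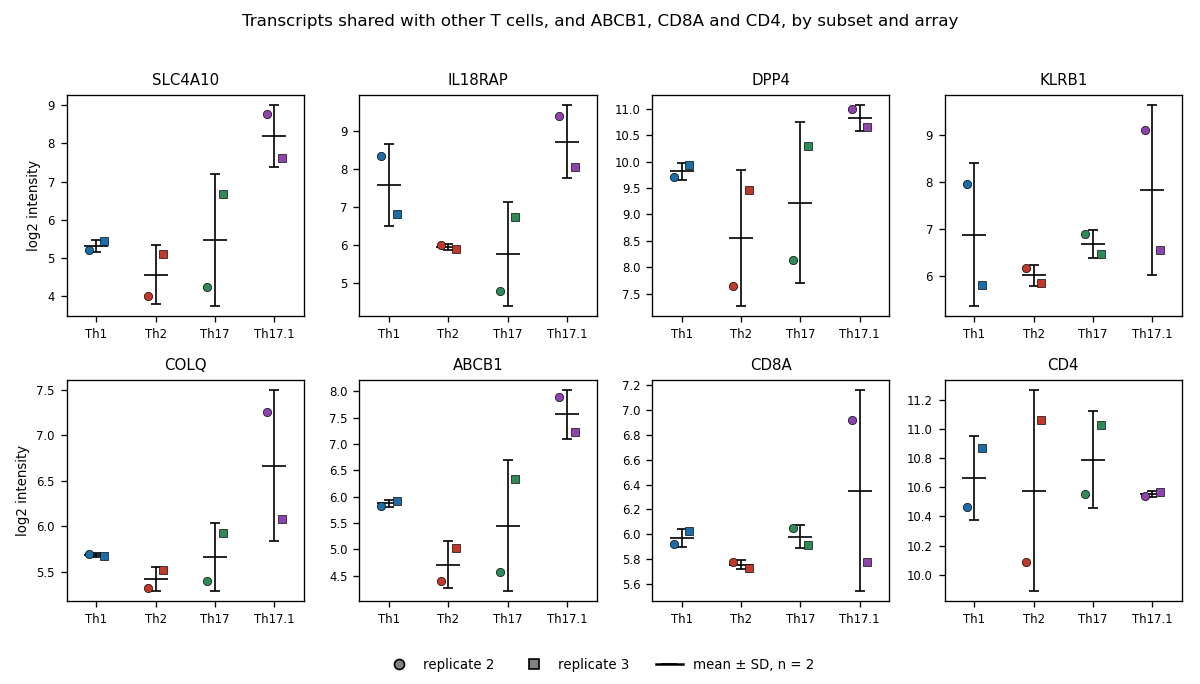
Log2 intensity (y axis) of 5 transcripts shared with MAIT or gamma-delta T cells, ABCB1, CD8A and CD4 by subset (x axis), with circles for arrays numbered 2, squares for arrays numbered 3 and bars for the mean ± SD of 2 arrays. SLC4A10, IL18RAP, DPP4 and ABCB1 are highest in both Th17.1 arrays of their number, while CD8A stands apart in Th17.1 replicate 2 alone.

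ABCB1 encodes P-glycoprotein, which pumps glucocorticoids and cytotoxic drugs out of cells. It measured 7.56 ± 0.46 (SD, n = 2) in Th17.1, 5.87 ± 0.06 in Th1, 5.45 ± 1.24 in Th17 and 4.71 ± 0.44 in Th2 cells. Among 22 measured ABC transporters it was the only member past the threshold adjusted over the list alone, in Th17.1 against Th2 cells, and it did not pass without Th2 replicate 2 or Th17.1 replicate 2. Without Th2 replicate 3 the count was 2. The list had no camera call in any contrast (Th17.1 against Th2 adjusted p = 0.130), and its median of -0.14 and its mean of 0.04 differ in sign.

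Lists without a camera call in any of the 9 contrasts were naive and central memory genes, glucocorticoid response, T cell activation, cholesterol synthesis, and markers of B cells, of monocytes and dendritic cells, and of platelets and red cells, each with 0 members past the threshold adjusted over the list alone. Between CCR4lo and CCR4hi cells the median was 0.15 for naive and central memory genes, 0.06 for glucocorticoid response, 0.03 for T cell activation, 0.10 for B cell markers and 0.07 for platelet and red cell markers, -0.002 for cholesterol synthesis and 0.003 for monocyte and dendritic cell markers. Chemokine receptors and integrins also had no camera call in any contrast, with adjusted p between 0.106 and 0.797. Up to 6 of 25 members passed adjusted over the list alone, in Th17 against Th1 cells. The 6 include CCR4 and CCR6, used for the sort, and CXCR3, named in the labels. That count was 0 without Th1 replicate 2, 1 without Th17 replicate 2 and 10 without Th17 replicate 3. IL2 measured 8.39 ± 0.27 (SD, n = 2) in Th1, 9.15 ± 0.34 in Th2, 8.42 ± 0.03 in Th17 and 8.67 ± 0.18 in Th17.1 cells.

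Subset differences were larger in the arrays numbered 2 than in those numbered 3. The SD over the 4 subsets exceeded 0.5 in 1009 rows among the arrays numbered 2 and in 180 among those numbered 3. Cytotoxicity genes differed between CCR4lo and CCR4hi cells by a mean of 1.82 in the first and 0.49 in the second. The signed difference, CCR4lo minus CCR4hi, was larger in the first for 17 of 18. Th17 genes differed between CCR6+ and CCR6- cells by 1.10 and 0.52. Across all rows the differences in the arrays of one number correlated with those of the other at Pearson r from 0.0715 for Th2 minus Th1 to 0.297 for Th17 minus Th1 over 8 contrasts, and at Spearman rho from -0.145 for CCR4lo minus CCR4hi to 0.199 for Th17 minus Th2. Without the dimmest 40% of rows r ran from 0.0969 for Th17.1 minus Th2 to 0.402 for Th17 minus Th1, and rho from -0.255 for CCR4lo minus CCR4hi to 0.293 for Th17 minus Th2. These correlations are across genes, which are not independent replicates. The receptors used for sorting followed the lists, with CCR6 differing by 2.41 and 1.07 between CCR6+ and CCR6- cells. CCR4 differed between CCR4lo and CCR4hi cells by -1.101 and -0.664. CXCR3, on which the labels disagree, differed between CCR4lo and CCR4hi cells by 2.01 and 0.80.

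**Figure D4:**
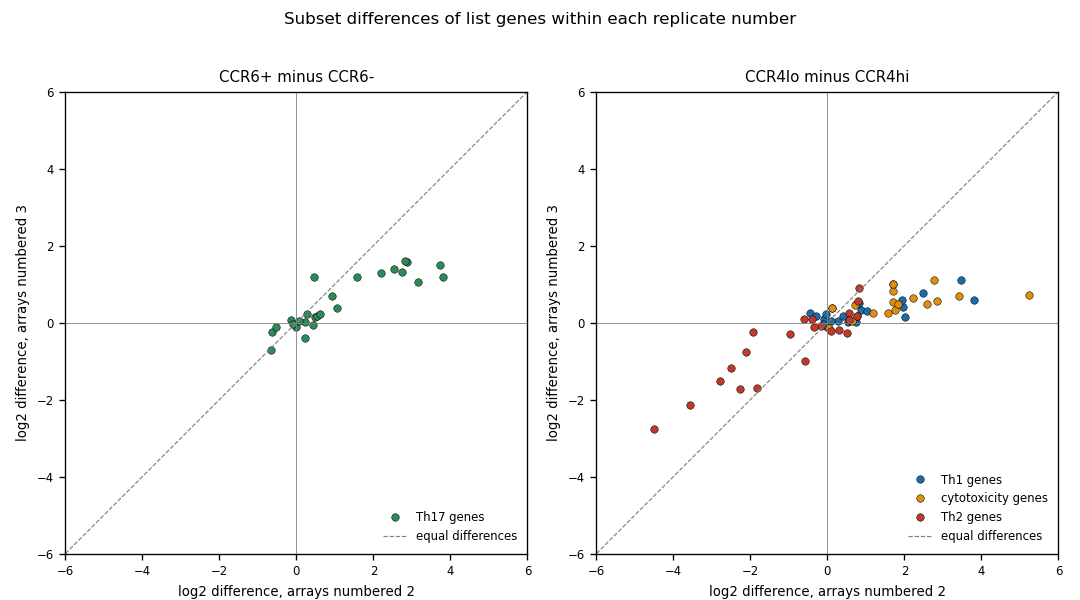
Log2 difference of each list gene within the arrays numbered 2 (x axis) and within those numbered 3 (y axis), for CCR6+ minus CCR6- subsets (left) and CCR4lo minus CCR4hi subsets (right), with each point a gene and a dashed line at equal differences. The signed difference, CCR4lo minus CCR4hi, is larger in the arrays numbered 2 for 17 of 18 cytotoxicity genes and 17 of 23 Th1 genes. That of CCR6+ minus CCR6- is larger there for 21 of 26 Th17 genes. For Th2 genes, with the sign turned to CCR4hi minus CCR4lo, this holds for 14 of 22.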

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

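The tests on the arrays of each number, except that of a single share of Th1 cells, and the test of CD8 transcripts were chosen after the results were seen. The counts over splits and the share of Th1 cells were planned.

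The effect of CCR6 differed between CCR4lo and CCR4hi cells in 4 lists, by camera's test of the interaction. The median interaction was -0.37 for Treg genes (adjusted p = 0.0454, and adjusted p = 0.473 with an estimated correlation), 0.297 for cell cycle genes (adjusted p = 0.000203, and adjusted p = 0.894 with an estimated correlation), -0.224 for NK cell markers (adjusted p = 0.00469, and adjusted p = 0.438 with an estimated correlation) and 0.336 for MAIT and gamma-delta T cell markers (adjusted p = 0.0454, and adjusted p = 0.757 with an estimated correlation). No member of these lists passed adjusted over the list alone. With the replicate number as a block the adjusted p of the MAIT list was 0.0744. The Treg call was lost without Th1 replicate 3, Th2 replicate 2, Th17 replicate 2 and Th17.1 replicate 3, at adjusted p of 0.273, 0.305, 0.168 and 0.155. The cell cycle call was lost without Th2 replicate 2, Th17 replicate 3 and Th17.1 replicate 3, at 0.736, 0.498 and 0.312, and the NK call without Th2 replicate 3, at 0.0648. The MAIT call was lost without Th1 replicate 3, Th2 replicate 2, Th2 replicate 3 and Th17 replicate 2, at 0.464, 0.0913, 0.166 and 0.167, and without Th17.1 replicate 2 its direction turned, at 0.790.

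Whether the counts exceed those of other groupings was tested over the 35 splits of the 8 arrays into 4 and 4. For the 9 Th17 genes past the threshold over the list alone by CCR6, 1 of 35 splits, the real one, gave as many, and the highest other gave 2. By CCR4 the real split gave 14 cytotoxicity, 8 Th1 and 7 Th2 genes in a fit of 4 arrays against 4, 1 of 35 splits gave as many in each case, and the highest others gave 3, 2 and 2. Each of these 4 counts met the bound set beforehand, a share of splits under 0.05. But 1 of 35 is the smallest share possible, and it was not adjusted over the several counts tested. Chance is therefore not excluded. The splits also took all 8 arrays as exchangeable, which the pairing of the arrays by number argues against. Among the 18 splits that hold as many arrays of each number in both arms as the real ones, too few for a share under 0.05, the real split alone gave as many, and the highest others gave 2, 3, 2 and 2. CCR6 gave 0 rows past the threshold, so that 35 of 35 splits gave as many by necessity, which says nothing about chance. For CCR4 chance is not excluded, with 1 row and 2 of 35 splits as many. At an unadjusted p under 0.05 CCR6 gave 863 rows and 17 of 35 splits as many, and CCR4 gave 917 rows and 15 of 35 splits as many. The highest other split parted the arrays by replicate number, with 2809 rows past the threshold and 6209 at an unadjusted p under 0.05, which points to a structure of the samples. Among the 18 splits balanced by number, 4 gave as many rows as CCR6 and 3 as many as CCR4 at an unadjusted p under 0.05.

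Subset differences were larger in the arrays numbered 2 than in those numbered 3. Random error that is independent between genes has no direction. Over 87 lineage genes the median difference in the direction of the gene's list was larger by 0.528. Its bootstrap SE was 0.122, and 0.247 when widened for the correlation within lists. These are the same list differences in which the pattern had been seen. The median lies only just over 2 widened SE from 0, and correlation between lists was not counted. The values are therefore only weak evidence against such independent error. An error shared by the genes of an array stays open, since the lists rest on the same 8 arrays. Cells of other subsets in the sorted cells of the arrays numbered 3 stay open: the differences in CCR6, CCR4 and CXCR3 were smaller there too, with a mean ratio of 0.482, but any cause that shrinks subset differences would give such a ratio, so it does not favour these cells. A single share of Th1 cells cannot be told apart from other causes: 6 Th1 transcripts in the Th17 array numbered 3 needed shares from 28.1% for NKG7 to 101% for GZMA, the last more than a mixture can hold, so that the highest was 3.589 times the lowest, past the bound of 3 set beforehand, but that bound took no account of the spread of a single array, and the Th2 array, whose shares ran from 33.6% to 67.8%, was added to the rule only after this value was seen. A difference between donors or in activation stays open as untested.

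Markers shared with MAIT and gamma-delta T cells were higher in the Th17.1 arrays, 8 of 9 lying above all other subsets in the arrays numbered 2 and 7 of 9 in those numbered 3. No gamma-delta receptor gene was among these 9. CD8+ cells of that kind inside the gate may add to this: CD8A and CD8B lay above the other subsets of the same number in 3 of 4 values, which neither excludes nor needs such cells. CD8A measured 6.92 against at most 6.05 in the arrays numbered 2 and 5.78 against at most 6.02 in those numbered 3. CD8B measured 5.26 against at most 5.06 and 5.42 against at most 5.35. A dimmer CD8B row differed in Th17.1 cells by 0.152 from Th1, 0.111 from Th2 and -0.229 from Th17 cells. The gate took CD4 cells, which would remove CD8+ cells, and the subset itself may express these genes, which was not tested. CD4 lay below the other subsets of the same number in Th17.1 replicate 3 but not in Th17.1 replicate 2.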

How the results depend on the processing

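The leave-one-out fits of the list tests, the fits of the compared arrays alone for named genes, the counts over a list alone under each alternative and the estimated correlation with the block were chosen after the data were seen. The other alternatives were planned.

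Some differences printed above, such as IFNG in Th17.1 against Th1 cells, were not among the 213 checked. None of these 213 reversed under the 14 or 15 alternatives run for each, an outcome largely fixed in advance. Many had been picked for non-overlapping groups, which leaving out an array cannot reverse. The block, the variance priors and the fits of the compared arrays leave the size of a difference unchanged. No row passed in the main fit, so a value could only stay uncalled or newly pass. Of their values under the alternatives, 3161 kept their side of the threshold and 13 newly passed it, 12 without Th17 replicate 3 and 1, IL17RB by CCR4, in a fit of 4 arrays against 4. Counts of rows past the threshold stayed within 1.5 times in 139 cases and moved in 9, and counts of lists called stayed in 85 and moved in 23. Counts over a list alone stayed within 1.5 times in 486 cases and moved in 234. Centring on the median, cyclic loess and the other variance priors gave 0 rows in each contrast, as did the replicate block, which is the fit that pairs the arrays by number.

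Between CCR4lo and CCR4hi cells a fit of 4 arrays against 4 gave 1 row, and the cause was not tested. With an estimated correlation, and with fry's directional test, 0 lists were called in all 9 contrasts, while fry's mixed test, for change in either direction, called Th2 genes in Th17.1 against Th2 (adjusted p = 0.0296) and by CCR4 (0.0265) and Th17 genes by CCR6 (0.0453). Across rows, the 2 CCR6 differences correlated at 0.145 within the arrays numbered 3, 0.345 within those numbered 2 and 0.307 in all, and the cause was not tested.

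Leaving out 1 array at a time, with a lone array assumed to vary like the other subsets, rows past the threshold ranged from 0 to 1 in Th2 against Th1, 0 to 28 in Th17 against Th1, 0 to 2 in Th17.1 against Th2, 0 to 23 in Th17.1 against Th17, 0 to 41 in CCR4lo against CCR4hi and 0 to 6 in the F test, and were 0 throughout in the other contrasts. Without Th17 replicate 3 the counts were 28, 2, 23, 41 and 6, without Th17 replicate 2 they were 2 in Th17.1 against Th2 and 6 by CCR4, and without Th2 replicate 3 the count was 1 in Th2 against Th1. Lists called ranged from 8 to 12 in Th2 against Th1, 5 to 8 in Th17 against Th1, 5 to 11 in Th17.1 against Th1, 3 to 10 in Th17 against Th2, 9 to 13 in Th17.1 against Th2, 8 to 12 in Th17.1 against Th17, 6 to 9 by CCR6, 9 to 13 by CCR4 and 2 to 9 in the interaction. These fits hold fewer samples and no block, so gained or lost calls mix a lone array's replicate number with its subset.

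The block changed 5 list calls. Those of Tfh genes in Th2 against Th1 (adjusted p = 0.0926), cell cycle genes in Th17 against Th1 (0.0819), cytokines in Th17 against Th2 (0.0818) and MAIT markers in the interaction (0.0744) were lost, and that of Tfh genes in Th17.1 against Th1 was gained (0.0146, and adjusted p = 0.356 in that fit with an estimated correlation). It changed no other call. The median of all rows moved by under 0.1 with each scaling. Background signal was not used here, so what dim signal hides is open.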

Other observations

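The comparison of arrays by replicate number was chosen after the results were seen. With subset terms in the fit, 1940 rows differed between the arrays numbered 3 and 2 past the threshold of limma, 1028 higher and 912 lower in those numbered 3. Naive and central memory genes had a median difference of 0.36 and chemokine receptors and integrins one of 0.31, both with a camera adjusted p of 0.00521 and an adjusted p of 0.984 with an estimated correlation. No other list was called.

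Same-numbered arrays of different subsets correlated at a mean of 0.991 over all rows, and arrays of the same subset at 0.987.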
